A study of Drosophila melanogaster with 2 samples.

How the data were processed

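Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of mixed sex, 6 to 16 hours old, from a transgenic line that carries Dmrt99B fused at its C-terminal end to eGFP. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 and, per their description, precipitated with an antibody against GFP, while their antibody entry names dmrt99B. The series held 1 group of 2 biological replicates, numbered 3 and 4 in the labels. There was therefore no comparison between groups, and the tests set the peaks against flanking, shuffled or matched sequence, random positions or other genes, or strong against weak peaks. P-values of these tests treat peaks or genes as the units, which are not independent replicates.

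The authors deposited 4 peak lists in coordinates of the dm6 genome build (release 6). These were a relaxed list for each replicate, a relaxed list from both replicates pooled, and a thresholded list. The last held peaks that passed a threshold on the irreproducible discovery rate (IDR), a measure of how well peak ranks recur between replicates. Per the text listing deposited with each sample, the relaxed lists were derived from the alignments and from a further file that is also a source of the control-normalised signal, and the IDR list from the 3 relaxed lists. That further file was not used here. The aligner, the peak caller and their versions are not given in the sources used here. Each relaxed list held 30000 peaks, so their lengths carry no information on the replicates. All 7838 IDR peaks were rows of the pooled list, and they were the 7838 pooled peaks with the highest signal value. The deposited signal value is a score that the authors' peak caller gave to each peak. Its scale is not stated and differed between lists, so it was used to describe, rank or filter peaks within a list, and between the replicate lists only for a correlation and a ratio that are given as descriptions. The deposited −log10 q values shared a top value in 7427 of the pooled peaks and were not used to rank. Read totals are not given in the sources used here, so the depth of each replicate is unknown. Each share is given with a 95% Wilson interval that covers counting error over peaks only, and not the spread between replicates.

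Peaks were placed on the release 6 reference sequence and on the gene annotation of Ensembl release 115. No peak ended beyond a chromosome arm of the reference. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Replicates were compared over the 7838 peaks of highest signal value in each, counting a summit as shared when a summit of the other replicate lay within 200 bp. Peaks per arm and genomic location were tested against 1000 random placements of the summits, over all arms or within the same arm, with two-sided empirical p-values. The smallest p these allowed before adjustment was 0.002. A summit was assigned, in this order of priority, to a promoter (within 500 bp of an annotated transcription start site, TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron or intergenic sequence.

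Windows of 201 bp centred on each summit were searched for 20 fixed motifs on both strands and compared, with an exact McNemar test, with a window of the same length 1000 bp to one side of the same summit. Every 7-mer present in at least 20 summit and flanking windows together was compared between them by an exact binomial test and ranked by log2 ratio. The relation of the DM core motif to peak strength was tested with 100000 permutations. A gene was called promoter-bound when an IDR summit lay within 1000 bp of one of its TSSs. For each of 21 gene lists the share of promoter-bound members was compared with that of all other protein-coding genes, 13945 in total, by a two-sided Fisher's exact test. Odds ratios were computed after adding 0.5 to each cell and are given with exact 95% intervals. In a separate test, the number of members with a summit in the gene body or nearest to their TSS was compared with 10000 random lists matched on locus length in 20 bins. P-values were adjusted within each family by the Benjamini-Hochberg method with a threshold of 0.05. Peaks around dmrt99B were counted within 20 kb of the gene and compared with 1000 random windows of the same length on arm 3R.

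The tests, the gene lists, the motifs and most alternatives were fixed before the data were examined. The genes named were those nearest to the 25 IDR peaks of highest signal value, up to 4 promoter-bound members of each list with the highest signal value, all DM-domain genes, and the 5 genes to which most IDR summits were assigned by nearest TSS. Results were also computed, each with those alternatives that apply to it, with a stricter peak set (the 3919 IDR peaks of highest signal value), each replicate alone (its 7838 strongest peaks), other distances and windows, a shuffled control that keeps dinucleotide counts, and the exclusion of promoter peaks. A control matched on GC content was added after the data were seen.

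The procedures were tested on simulated summits. Over 5 sets of 7838 random summits, 1 of 30 arm tests, 0 of 35 location tests, 1 of 100 motif tests, 0 of 40960 7-mer tests, 2 of 105 gene list tests and 0 of 105 length-matched list tests passed the threshold. These summits were placed uniformly, without the lower GC content or the promoter share of the real ones. The rates therefore do not give the error of the motif, 7-mer and list tests on the real peaks. With the DM core put into 10 percent of the windows, the 7-mer ranked first of 8192, and 12.5% of windows carried the motif where 12.9% were expected with those already present by chance. A list with a summit placed at 18 of its 30 genes was called by both list tests.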

Results

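Dmrt99B is a transcription factor of the DM-domain family, named for the DNA-binding domain it shares with the sex determination factor doublesex. The data were ChIP-seq peaks for its eGFP fusion in whole embryos 6 to 16 hours old, with 1 group of 2 biological replicates. The question addressed was where the fusion protein was recovered on the genome. With no second group, the comparisons were those between replicates, and between bound sequences or genes and the remainder of the genome. Read depth was unknown. The intervals given cover counting error over peaks or genes only, and do not measure the spread between the 2 replicates.

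The strongest peaks recurred in both replicates. Of the 7838 peaks of highest signal value in replicate 3, 6688 (85.3%, 95% Wilson interval 84.5% to 86.1%) had a summit within 200 bp of one of the 7838 strongest of replicate 4, and 84.5% of those of replicate 4 were shared in the other direction. Randomly placed summits shared 2.34% on average over 100 draws, and at most 229 peaks. A peak of each replicate covered the summit of 7686 IDR peaks. Across these peaks the log2 signal values of the replicates correlated with a Pearson r of 0.917 and a Spearman rho of 0.878. These values describe peaks and not independent replicates. The peaks were also selected, for high pooled signal value and for a peak in both replicates, so the correlation was not taken over an unselected set. Of the IDR peaks, 56 had no replicate 3 peak over the summit and 98 had no replicate 4 peak. The signal value was 2.50 times higher in replicate 3 at the median peak, and since the scale of the value is not stated this ratio was not read as a difference in binding. The shared percentage was 69.3% when summits had to lie within 50 bp, and 92.2% for the top 1000 peaks of each replicate.

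**Figure D1:**
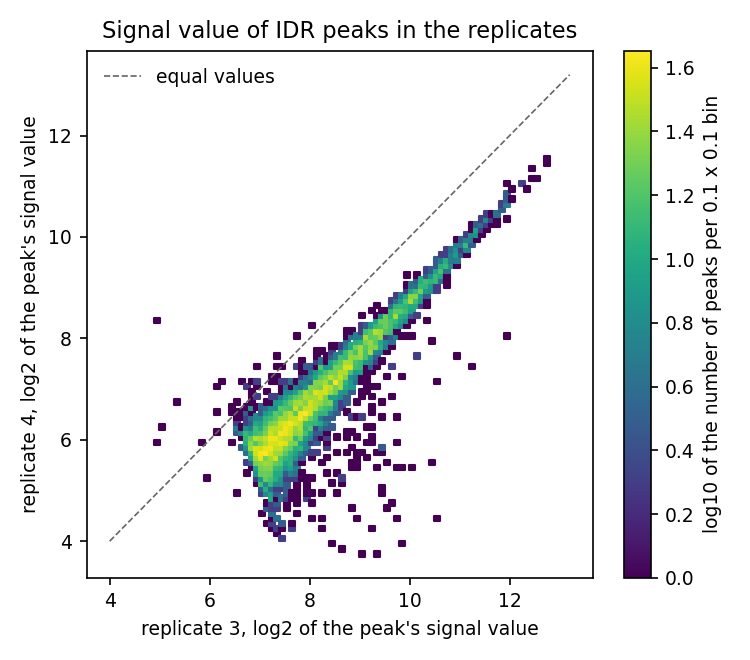
Signal value of 7686 IDR peaks in replicate 3 (horizontal axis, log2) and replicate 4 (vertical axis, log2), with colour giving the log10 number of peaks per bin and the dashed line marking equal values. The peaks follow a band below the line (Pearson r 0.917), in which the median ratio of replicate 3 to replicate 4 was 2.50.

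The IDR set held 7838 peaks with a median width of 402 bp. Together they covered 2616 kb, or 1.95% of the chromosome arms, and formed 7496 intervals once overlapping ones were merged. Their signal value, which is the authors' own score, ranged from 169 to 9896 with a median of 341. The 25 strongest peaks lay among the top 26 of replicate 3 and the top 25 of replicate 4. Of these 25, 16 had their summit in a promoter, 6 in an intron, 2 in intergenic sequence and 1 in an exon of a non-coding RNA.

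The strongest peak (signal value 9896) lay at the promoter of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, on X from 2703631 to 2704155 with its summit 28 bp from a TSS. The next (9682, 2L from 480523 to 481368) lay in an intron of ush, a cofactor of GATA factors, 1369 bp from the TSS of cbt, a zinc-finger transcription factor. Peaks followed at the promoter of CG14100 (8293), in an exon of the non-coding RNA lncRNA:Vinr with CG4004 as the nearest protein-coding gene (8193), and in an intron of CG11050 (8175). Further peaks among the 25 lay at or in ph-p, a Polycomb group gene (6025, promoter), Trl, which encodes GAGA factor (5878, intron), HmgZ, an HMG-box protein (5694, intron), Chro, a chromodomain protein (5304, promoter), and the nuclear receptor Hr3 (5209, intron). Promoter peaks were also found at mRpL41 of the mitochondrial ribosome (6938), the arginine methyltransferase Art3 (6094), the isomerase Fkbp14 (5812), PNPase (5757) and the glycolytic enzyme gene Gapdh2 (5557). The remaining peaks lay nearest to px (7072), CG18549 (6836), CG13323 (6090), Tina-1 (5647), CG1635 (5645), tara (5633), CG31145 (5603), CG32772 (5587), CenG1A (5472) and CG13390 (5217). The genes to which most summits were assigned were CG43245 and shn (20 summits each), rdx (18), CHES-1-like (17) and px, tara, Tlk, CG6163, Eip75B and hng3 (16 each, of which px had the highest signal value).

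Peaks were unevenly spread over the chromosome arms. The X carried 67.0 peaks per Mb (95% Poisson interval 63.7 to 70.4), 1.14 times the density of uniform placement, and 2L carried 62.4 per Mb (ratio 1.06). Density was lower than uniform on 2R (51.8 per Mb, ratio 0.883) and 3R (55.0 per Mb, ratio 0.938), and lowest on the small chromosome 4, where 16 peaks gave 12.0 per Mb (ratio 0.205). These 5 arms passed the permutation test (adjusted p between 0.0040, from the smallest p that 1000 placements can give, and 0.0096), and 3L did not (61.1 per Mb, ratio 1.04, permutation test, adjusted p = 0.064). In the same permutation test the call for 2L was lost in the 3919 strongest peaks (adjusted p = 0.24) and without replicate 4 (0.058), but not without replicate 3 (0.0090). Arm 3L passed without replicate 3 (permutation test, adjusted p = 0.04995) and without replicate 4 (0.019), but not in the 3919 strongest peaks (0.23). Placement was uniform over all sequenced bases and took no account of repeats or of where reads can be placed. Whether these lowered the density on chromosome 4 or other arms was not tested.

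Summits were concentrated in promoters and almost absent from coding exons. Promoters held 2282 summits, or 29.1% (Wilson interval 28.1% to 30.1%), against 13.1% of random positions within the same arm. Coding exons outside promoters held 18 summits, or 0.230% (0.145% to 0.363%), against 13.7% of random positions. The 3′ UTRs were also underrepresented, at 0.944% against 4.47%, as were 5′ UTRs (0.536% against 0.784%) and intergenic sequence (20.5% against 27.3%). Introns held 47.3% of summits against 39.7% of random positions, and exons of other kinds 1.31% against 0.935%. All 7 classes passed the permutation test (adjusted p between 0.0028, from the smallest p that 1000 placements can give, and 0.014). Against random positions matched on GC content, a control chosen after the data were seen, 5′ UTRs did not pass the permutation test (ratio 0.940, adjusted p = 0.77; between 0.0023 and 0.040 under the other alternatives). Coding exons held 0.0603 times the matched number of summits (permutation test, adjusted p = 0.023, from the smallest p that 100 placements can give). Exons of other kinds did not pass with a promoter window of 1000 bp or in the 3919 strongest peaks (permutation test, adjusted p = 0.106 and 0.110).

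**Figure D2:**
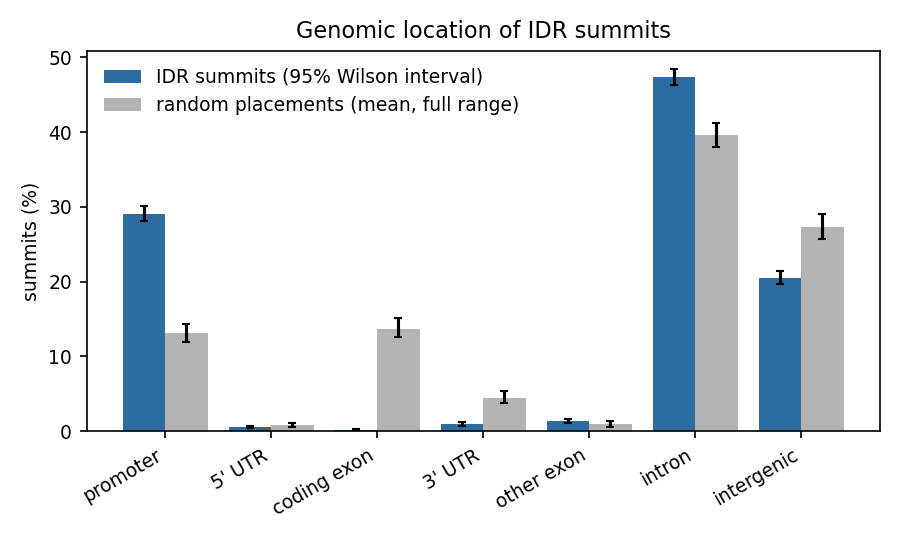
Percentage of the 7838 IDR summits (blue, bars with 95% Wilson intervals) and of random positions in the same arm (grey, mean and full range of 1000 placements) in 7 classes of location. Promoters held 29.1% of summits against 13.1% of random positions, and coding exons 0.230% against 13.7%.

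The share of promoters was highest among the strongest peaks. It was 52.6% in the 10% of IDR peaks with the highest signal value, 36.6% and 29.7% in the next sets of equal size, and between 22.96% and 26.3% in all weaker sets. Among the pooled peaks below the IDR threshold, 16.8% had their summit in a promoter and 1.08% in a coding exon. Of the summits in promoters, 78.8% lay upstream of the nearest TSS, with a median position of -149 bp and quartiles of -260 and -24.3 bp.

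The DM core sequence ACAWTGT, taken here as the site of DM-domain proteins, was only slightly more frequent at summits than beside them. Only exact matches were counted, so a site of Dmrt99B that differs from this sequence would be missed. The DM core occurred in 313 of 7838 summit windows (3.99%, Wilson interval 3.58% to 4.45%) and in 262 flanking windows (3.34%), a log2 ratio of 0.26 (exact McNemar test, adjusted p = 0.048). The longer doublesex-type site RNNACWAWGTNNY was found in 271 summit windows against 184 flanks (log2 ratio 0.56, exact McNemar test, adjusted p = 8.2e-05). Summit windows had a lower GC content than flanks, 34.0% ± 7.38 against 41.2% ± 8.82 (SD over 7838 windows). Neither site was enriched over windows matched on GC content, where the log2 ratios were 0.0092 and 0.049 (exact McNemar test, adjusted p = 1 and 0.85), nor over shuffled summit windows (-0.14 and -0.057, adjusted p = 0.27 and 0.73). The call for the DM core over flanks was also lost in the 3919 strongest peaks (log2 ratio 0.37, exact McNemar test, adjusted p = 0.054), without replicate 3 (0.24, 0.069) and in windows of 200 bp to either side (0.18, 0.062). That for the longer site was lost outside promoters (log2 ratio 0.30, exact McNemar test, adjusted p = 0.069). In the 3919 strongest peaks the DM core ratio was higher than over all peaks, with fewer peaks tested. The DM core over flanks passed outside promoters (log2 ratio 0.61, exact McNemar test, adjusted p = 6.0e-05), where no GC-matched comparison was made, without replicate 4 (0.50, 6.8e-05) and in windows of 50 bp to either side (0.49, 0.0078). The DM core was no more frequent in strong than in weak peaks (Spearman rho 0.0042, permutation p = 0.71). It was present in 4.47% of the strongest 10% of peaks and 3.70% of the weakest 10%.

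Other motifs differed from the flanks as well. Higher frequencies at summits were found for the core promoter sequences DRE (TATCGATA, 104 windows against 51, log2 ratio 1.02), M1BP motif 1 (GGTCACACT, 46 against 18, 1.33) and TATA box (TATAAAAG, 214 against 115, 0.89), and for the homeodomain (1488 against 1065, 0.48), forkhead (480 against 372, 0.37) and GATA (583 against 512, 0.19) sequences. Of these, DRE, M1BP motif 1, forkhead and GATA also exceeded windows matched on GC content (adjusted p between 0.0018 and 0.0040). TATA box did not (log2 ratio 0.048, exact McNemar test, adjusted p = 0.85), and homeodomain fell on the other side of 0 (-0.092, adjusted p = 0.10). Outside promoters DRE and M1BP motif 1 were not enriched over flanks (-0.56 and -0.36, exact McNemar test, adjusted p = 0.20 and 0.71). TATA box did not pass against shuffled windows either (exact McNemar test, adjusted p = 0.73), where homeodomain was called lower (-0.20, 1.4e-05). In the 3919 strongest peaks M1BP motif 1 and GATA did not pass (exact McNemar test, adjusted p = 0.25 and 0.59), and in windows of 50 bp to either side they and DRE did not (0.32, 0.12 and 0.27), nor did GATA in windows of 200 bp (0.30). Lower frequencies at summits were found for E-box CACGTG (101 against 181, -0.84), Nkx2 (162 against 272, -0.75), CA repeat (264 against 433, -0.71), Runx (287 against 447, -0.64), E-box CAGCTG (451 against 654, -0.54), POU (242 against 307, -0.34) and GAGA (243 against 306, -0.33). Most of these lower frequencies depended on the control. Of the 7 motifs, only Runx was also called lower against GC-matched windows (-0.42, exact McNemar test, adjusted p = 0.0018). E-box CACGTG, Nkx2, POU and E-box CAGCTG did not pass there (exact McNemar test, adjusted p = 0.10, 0.40, 0.23 and 0.13), and GAGA and CA repeat were called higher (0.89 and 0.33, adjusted p = 6.0e-08 and 0.038). Against shuffled windows GAGA, CA repeat, E-box CAGCTG, POU and Nkx2 were all called higher (1.89, 2.20, 0.91, 0.32 and 0.47, adjusted p between 3.8e-33 and 0.032). Runx and E-box CACGTG were still called lower there (-0.37 and -0.47, exact McNemar test, adjusted p = 0.0020 and 0.022). In windows of 200 bp to either side GAGA was called higher (0.40, exact McNemar test, adjusted p = 6.1e-07), and CA repeat and E-box CAGCTG did not pass (0.27 and 0.89). Over flanks, GAGA did not pass without replicate 4 (exact McNemar test, adjusted p = 0.052). POU did not pass without replicate 3, in the 3919 strongest peaks or in windows of 50 bp (exact McNemar test, adjusted p = 0.13, 0.25 and 0.43). Sox, Zelda, Grainyhead, Su(H) and AP-1 sequences did not pass the test against flanks (adjusted p between 0.056 and 0.34), but some did under alternatives. Su(H) passed as lower in each replicate alone, in windows of 50 bp and outside promoters (exact McNemar test, adjusted p = 4.7e-05, 2.6e-05, 0.0012 and 0.0046), and as higher against shuffled windows (0.71, 2.1e-04). Grainyhead passed as lower without replicate 3 and Sox outside promoters (exact McNemar test, adjusted p = 0.027 and 0.021).

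A search without a preset motif ranked a different sequence first. Of 8192 7-mers, 1459 were more frequent at summits than in flanks and 3426 less frequent. Summit windows were lower in GC than flanks, and the full set of 7-mers was not compared with GC-matched windows. These counts may therefore reflect base composition. The top 7-mer, CAGTGTA, was present in 660 summit windows (8.42%) and 136 flanks (1.74%), a log2 ratio of 2.27 (exact binomial test, adjusted p = 7.2e-80). It was followed by the overlapping CACTGAG (526 against 164, 1.68) and AGTGTAG (336 against 118, 1.51). The DM core 7-mer ACAATGT ranked 1767 (log2 ratio 0.26, exact binomial test, adjusted p = 0.060). With its reverse complement it is the DM core ACAWTGT, so these are the same 313 and 262 windows under another test. It passed the exact binomial test outside promoters (0.61, adjusted p = 1.7e-04) and without replicate 4 (0.50, adjusted p = 1.65e-04), but not without replicate 3 (0.24, adjusted p = 0.093). CAGTGTA ranked first in each replicate alone, in the 3919 strongest peaks and outside promoters. Its matches peaked 75 to 100 bp to either side of the summit, at 20.4 and 20.03 matches per 1000 peaks in 25 bp, and fell to 3.57 and 3.70 in the bins next to the summit.

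**Figure D3:**
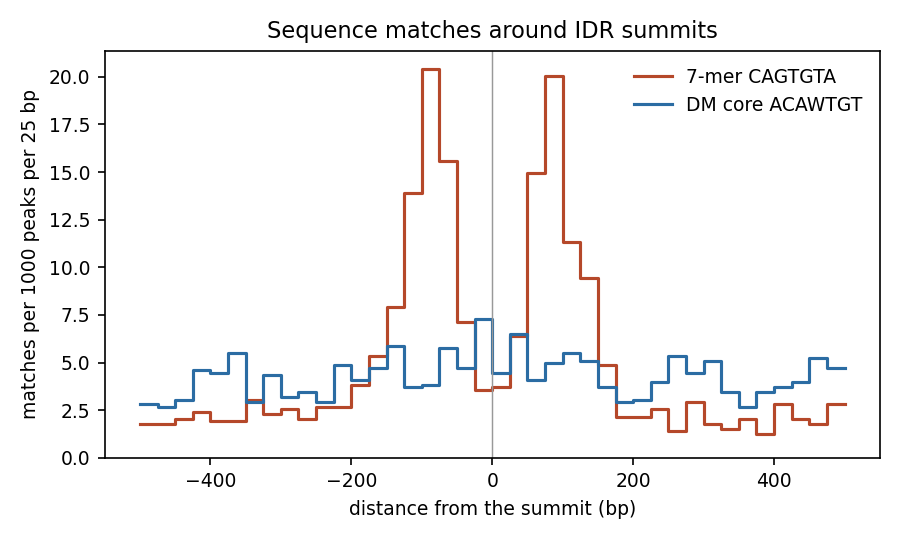
Matches per 1000 IDR peaks in bins of 25 bp (vertical axis) against distance from the summit in bp (horizontal axis) for the 7-mer CAGTGTA and the DM core ACAWTGT. CAGTGTA rose to 20.4 and 20.03 matches at 75 to 100 bp on either side, and fell to 3.57 and 3.70 beside the summit.

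Of 13945 protein-coding genes, 2807 (20.1%) were promoter-bound, and 3 of 21 gene lists exceeded the other genes. Ribosomal protein genes stood out, with 54 of 92 bound (58.7%, odds ratio 5.71, exact 95% interval 3.71 to 8.94, Fisher's exact test, adjusted p = 9.9e-15). Their strongest peaks lay at RpL34b (signal value 1304), RpS27 (1276) and RpS28b (1040). Glial genes followed with 7 of 10 bound (odds ratio 8.52, exact interval 2.12 to 55.6, adjusted p = 0.0094), among them moody, a receptor of the blood-brain barrier (1790), Gli, a septate junction protein (879), the FGF receptor htl (814) and pnt, an ETS factor of receptor tyrosine kinase signalling (524). Of the Notch pathway, 9 of 18 genes were bound (odds ratio 3.98, exact interval 1.40 to 11.3, adjusted p = 0.031), with numb, an inhibitor of Notch (2487), E(spl)m3-HLH (2270), E(spl)m7-HLH (1525) and the ubiquitin ligase gene neur (1112) as the strongest. Promoter peaks of the bound E(spl) genes all lay between 25997040 and 26036899 on 3R, and the test treats these neighbours as independent. In Fisher's exact test the call for glial genes was lost in the 3919 strongest peaks (adjusted p = 0.058) and with a TSS distance of 5000 bp (0.099), with adjusted p between 0.00995 and 0.018 under the other alternatives. That for Notch pathway genes was lost in both of these settings (0.33 and 0.080) and without replicate 3 (0.14), with adjusted p between 0.0049 and 0.027 under the others.

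**Figure D4:**
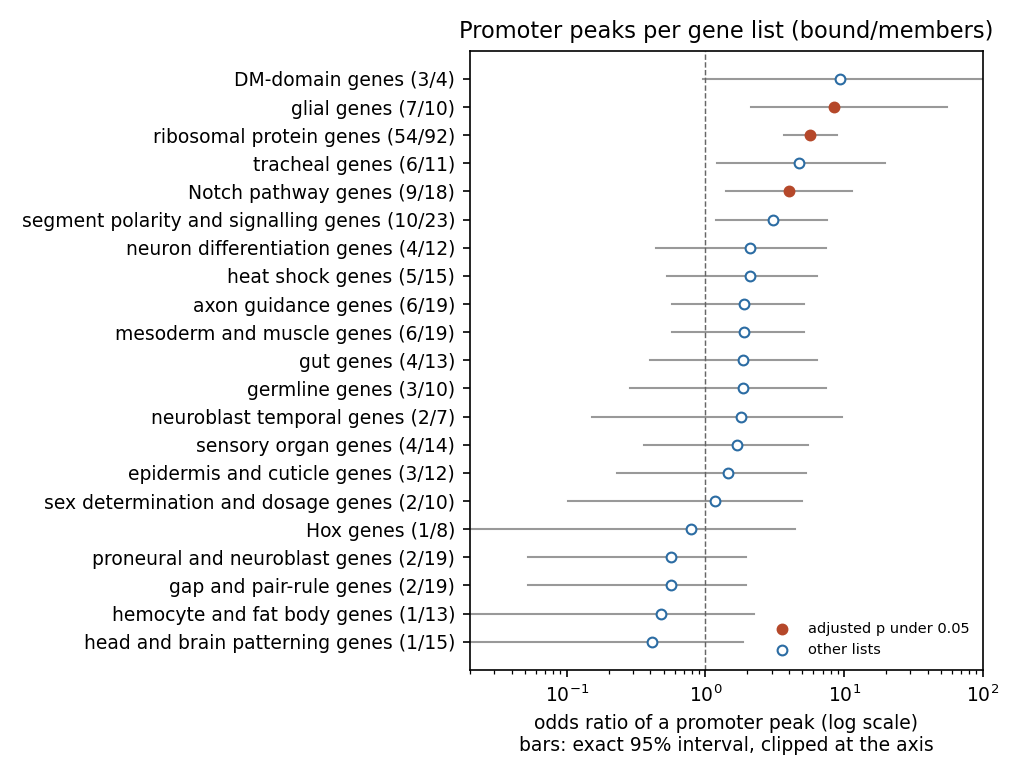
Odds ratio of a promoter peak for 21 gene lists against all other protein-coding genes (horizontal axis, log scale), with exact 95% intervals clipped at the axis and the numbers of bound genes and members beside each name. Filled points mark the 3 lists with an adjusted p under 0.05: glial genes (8.52), ribosomal protein genes (5.71) and Notch pathway genes (3.98).

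No list passed with fewer bound genes than expected, and 6 lists had an unadjusted p under 0.05. The other 3 of these were the tracheal genes (6 of 11 bound, Fisher's exact test, adjusted p = 0.063), with trh (signal value 1678), dysf (720), pyd (653) and ush (542), the segment polarity and signalling genes (10 of 23, adjusted p = 0.063), with the EGF receptor ligand gene spi (2231), its inhibitor aos (1447), nkd (1302) and pnt, and the DM-domain genes (3 of 4, adjusted p = 0.097). The bound DM-domain genes included the tagged gene dmrt99B itself, where the transgene may add reads. Segment polarity and signalling genes passed Fisher's exact test without replicate 4 (adjusted p = 0.022), and they and tracheal genes passed with a TSS distance of 500 bp (0.014 and 0.018). Among genes of the nervous system, 4 of 12 neuron differentiation genes were bound, led by elav (3766), fne (581), Syx1A (322) and Rbp6 (211). Bound members numbered 6 of 19 axon guidance genes, with unc-5 (1711), PlexA (925), Sema1a (394) and Fas2 (265), and 2 of 19 proneural and neuroblast genes, brat (3126) and nerfin-1 (279). Counts were 2 of 7 for neuroblast temporal genes (grh 702, pdm2 176), 1 of 15 for head and brain patterning genes (so 575) and 4 of 14 for sensory organ genes (Dll 287, rho 284, Poxn 250, dac 180). Of the early patterning genes, 1 of 8 Hox genes (Antp 284) and 2 of 19 gap and pair-rule genes (bcd 454, hry 172) were bound.

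In the other tissues, 6 of 19 mesoderm and muscle genes were bound, including sls (1383), tin (1365), Tm1 (854) and Mef2 (288), as were 4 of 13 gut genes (fkh 728, peb 327, GATAe 265, srp 182), 1 of 13 hemocyte and fat body genes (srp) and 3 of 12 epidermis and cuticle genes (grh, sn 478, Ddc 423). Bound genes numbered 3 of 10 in the germline list (gcl 525, vas 357, nanos 218), 2 of 10 in the sex determination and dosage list (Sxl 1101, fru 374) and 5 of 15 heat shock genes, with Hsp27 (3465), Hsp83 (1075), Hsp26 (934) and Hsp22 (699). None of these lists passed the test (adjusted p between 0.58 and 1). When each summit was assigned to the nearest TSS at any distance, 8 further lists passed Fisher's exact test. These were the segment polarity and signalling (odds ratio 12.5), Hox (14.4), axon guidance (7.60), tracheal (6.99), sensory organ (6.72), gut (4.45), head and brain patterning (4.21) and mesoderm and muscle genes (3.89), with adjusted p between 2.0e-07 and 0.013. This assignment favours genes with long loci, and with lists matched on locus length 7 of the 8 did not pass (adjusted p between 0.13 and 0.83).

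When lists were matched on locus length, ribosomal protein genes again exceeded random lists, with a summit in the locus of 52 of 92 genes against 17.1 on average (permutation test, adjusted p = 0.0042, from the smallest p that 10000 random lists can give). Segment polarity and signalling genes did so as well, with 21 of 23 against 13.9 (central 95% of random lists 9 to 18, permutation test, adjusted p = 0.023), but not without replicate 3 (adjusted p = 0.36; between 0.0147 and 0.027 under the other alternatives). Notch pathway genes (11 of 18 against 6.67, adjusted p = 0.21) and glial genes (7 of 10 against 4.01, adjusted p = 0.39) did not pass this permutation test, although Notch pathway genes did when matched on gene body length (excess of 5.48 genes, adjusted p = 0.027), and 4 lists had an unadjusted p under 0.05.

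The tagged gene itself lay in a region with many peaks. dmrt99B (FBgn0039683, 3R from 29692591 to 29697025) had no summit within its body and 4 IDR summits nearest to its TSS. A pair of these lay in the promoter, at 3R from 29692218 to 29692442 (signal value 398, rank 3342, no replicate 3 peak over the summit) and from 29692426 to 29692568 (228). The others were intergenic, at 29699254 to 29699555 (442) and 29701464 to 29701887 (174). Within 20 kb of the gene, 10 IDR peaks were counted against a median of 1 in random windows of 3R (percentile 98.0), and 28 pooled relaxed peaks against a median of 7 (percentile 96.3). The count of relaxed peaks was 29 in replicate 3 (percentile 96.6) and 25 in replicate 4 (percentile 95.1). The strongest IDR peak of this region (773) lay nearest to Obp99c, an odorant-binding protein gene, at 29690377 to 29690856. Of the other DM-domain genes, dmrt11E had 1 summit at its promoter (signal value 692) and dsx had 2 summits, the stronger of 483 at its promoter. No IDR summit was assigned to dmrt93B.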

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

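The test of where CAGTGTA lies relative to the summit was chosen only after the result was seen. Pooled peaks below the IDR threshold entered no sequence comparison of the report. A count over their windows was set against the flanks because the main measurement leaves these peaks out. Peaks overlapping an IDR peak were not removed, so some of the windows may hold the same matches as IDR windows. The 30000 pooled peaks formed 25249 intervals once overlapping ones were merged. Of 22162 such peaks, 794 (3.58%, Wilson interval 3.35% to 3.84%) carried CAGTGTA at the summit, against 431 flanks (1.94%, 1.77% to 2.14%; log2 ratio 0.88, exact McNemar test, p = 5.9e-26). The DM core was present in 703 of these summit windows and 704 flanks.

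CAGTGTA stood over the flanks at IDR summits while the DM core hardly did. Base composition was argued against, since shuffled summit windows carried the 7-mer at 21.2% of the real share (interval 17.7% to 25.5%). Promoter sequence did not account for it either, as the log2 ratio outside promoters was 2.45 (2.14 to 2.76). Annotated transposable elements did not supply the matches, as 0 of the 660 matching windows had the 7-mer inside one (upper Wilson bound 0.579%). Repeats outside that annotation were not examined, so other repeated sequence carrying the 7-mer was not tested. Summits were not centred on the 7-mer: the density of matches within 25 bp of the summit was 22.8% of that in bands starting 50 bp to either side (17.4% to 29.7%). This restates the positions already seen. It argues against protein bound at the 7-mer only if a summit marks the bound base, which was not tested. A sequence bound beside the peak centre, or fragment ends that favour it, may still be behind the pattern; neither was tested, and reads were not used here.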

How the results depend on the processing

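The comparison with GC-matched positions or windows was chosen after seeing the data; all other alternatives were planned. Of 469 values under alternatives, 356 kept their direction and their side of the threshold, or stayed within their interval or, for counts, within a fixed factor of the main value. The promoter excess, the deficit in coding exons and 3′ UTRs, the low density on chromosome 4 and the first rank of CAGTGTA held under every alternative run on them. None of the alternatives changed the uniform placement used for the arms. The cause of the changes below was not tested unless stated. Depth was unknown, so its effect on the peak lists and ranks could not be assessed. No paired analysis was possible because there was 1 group.

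Of the top peaks of replicate 3, 69.3% were shared within 50 bp, 86.4% within 500 bp, 69.5% with intervals overlapping by 50% and 92.2% in the top 1000. The percentile of IDR peaks at dmrt99B was 96.1 within 50 kb, and that of pooled peaks 98.2 within 10 kb and 89.5 within 50 kb.

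With each replicate alone, the arm ratio was 1.05 to 1.06 on 2L and 1.04 to 1.05 on 3L, and the log2 ratio of the DM core and of ACAATGT was 0.24 to 0.50. The odds ratio was 0.808 to 1.76 for neuroblast temporal genes and 0.773 to 1.35 for Hox genes. Matched on locus length, 1 to 2 lists were called, and the excess of germline genes over random lists was -0.727 to -0.632 genes.

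In the 3919 strongest peaks, the ratio was 1.04 on 2L and 1.29 for other exons, neither still called, the DM core had a log2 ratio of 0.37 (no longer called, with fewer peaks tested), and 1 list was called. Odds ratios fell below 1 for sensory organ genes (0.227) and gut genes (0.789). The excess over length-matched lists was -2.29 for sensory organ, -0.789 for germline and 0.320 for sex determination and dosage genes.

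With a promoter window of 1000 bp the ratio for other exons was 1.25, and against GC-matched positions that for 5′ UTRs was 0.940. In motif windows of 200 bp to either side the log2 ratios were 0.18 for the DM core, 0.40 for GAGA (called higher) and 0.011 for E-box CAGCTG. In windows of 50 bp that of Sox was 0.0035.

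Against shuffled windows, the log2 ratio turned to -0.14 for the DM core, -0.057 for the longer DM site and -0.20 for homeodomain. It turned positive for GAGA (1.89), E-box CAGCTG (0.91), CA repeat (2.20), Grainyhead (0.18), POU (0.32), Su(H) (0.71) and Nkx2 (0.47). Of these reversals, all but those of the DM sites and Grainyhead passed the threshold in the new direction; over all alternatives 12 of 48 reversals did. Against GC-matched windows it was 0.0092 for the DM core, 0.049 for the longer DM site, 0.89 for GAGA and 0.33 for CA repeat, both called higher, 0.18 for E-box CAGCTG, -0.092 for homeodomain, 0.31 for Su(H) and 0.13 for AP-1.

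Without promoter peaks, the log2 ratio was 0.30 for the longer DM site, -0.56 for DRE, -0.36 for M1BP motif 1 and 0.61 for ACAATGT, and the Spearman rho of the DM core with signal value was -8.7e-04.

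The number of lists called was 5 with TSSs within 500 bp, 1 within 5000 bp and 11 with the nearest TSS at any distance. At 500 bp the odds ratio was 1.04 for Hox genes and 0.680 for epidermis and cuticle genes. At 5000 bp it was 0.667 for neuroblast temporal, 1.30 for head and brain patterning, 0.850 for sensory organ, 1.47 for Hox and 0.685 for sex determination and dosage genes. With the nearest TSS at any distance it was 1.72 for proneural and neuroblast, 4.21 for head and brain patterning and 14.4 for Hox, both called, 2.13 for gap and pair-rule, 1.36 for hemocyte and fat body, and 0.845 for both germline and sex determination and dosage genes. Matching on gene body length gave an excess of 2.19 for proneural and neuroblast, 3.15 for gap and pair-rule and -0.473 for germline genes.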

Other observations

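The tests of match orientation, splice acceptors, start sites, sequence context, GC-matched positions and mitochondrial ribosomal protein genes were chosen only after the results were seen. Within 150 bp of IDR summits there were 1037 matches to CAGTGTA. In 847 peaks a match pointed away from the summit when read from C to A, in 116 peaks a match pointed toward it, and 62 peaks had outward matches on both sides. Upstream of the 7-mer a run of T was common: T made up 72.0%, 75.8% and 71.3% of bases at positions -7, -6 and -5, counted from the base before its first C. Only 4 of the matches ended their CAG at an annotated splice acceptor, and 3 lay within 10 bp of an annotated TSS on the same strand. The 7-mer was present in 9.67% of peaks outside promoters and 5.39% of promoter peaks, against 1.76% and 1.10% of their flanks, and in 7.66% of the strongest 10% and 8.93% of the weakest 10% of IDR peaks. Mitochondrial ribosomal protein genes, looked at because mRpL41 was among the strongest peaks, were bound at 20 of 73 promoters (odds ratio 1.52, Fisher's exact test, p = 0.14).

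Peaks concentrated at promoters and avoided coding exons. The low GC content of the bound windows did not account for the whole coding exon deficit. Matching on arm and GC content lowered the random share from 13.7% to 3.81% (range 3.13% to 4.30% over 100 placements), against 0.230% of summits. Whether GC content accounted for part of it cannot be told from this, since windows that avoid coding exons may be low in GC for that reason. Reads recovered at highly transcribed promoters whatever the protein remain a candidate explanation for the promoter share, given the odds ratio of 5.71 for ribosomal protein genes. That value rests on the presence of a peak and does not separate this from binding of the fusion, and transcription was not measured. The strongest peak at these genes, at RpL34b, ranked 694 by signal value, while the promoter share was highest (52.6%) in the strongest 10% of peaks. Binding of divergent promoter pairs was left open by its test. Genes with a protein-coding TSS on the opposite strand within 1000 bp had an odds ratio of 1.76, but a summit near such a pair counts for both genes, and a pair of independent promoters at the rate of the other genes (16.7%) would give 30.6% bound, above the 26.0% found. A precipitation from embryos without the fusion was not analysed here.

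The transgene may add reads around dmrt99B through extra copies of the cloned region. The percentile of 96.3 for pooled relaxed peaks within 20 kb (Wilson interval 94.9 to 97.3) lay between the bounds set for and against this. Both extra copies and binding would raise the count, so it cannot tell them apart at any percentile. The percentile was higher within 10 kb (98.2) and lower within 50 kb (89.5), and the extent of the cloned region is not given in the sources used here.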
